A study of Homo sapiens with 4 samples.

How the data were processed

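RNA sequencing was performed on MDA-MB-231 cells, an established human triple-negative breast cancer cell line. The 4 libraries formed 2 groups by their titles and source descriptions, with 2 untreated libraries and 2 libraries of cells given a small interfering RNA against PCBP2 (siPCBP2). One treatment field of the siPCBP2 samples speaks of transfection with PCBP2 itself, in conflict with their titles and source descriptions; the grouping followed the latter, and the level of PCBP2 in every library is reported first as a check. The untreated cells received no control RNA according to the labels, so transfection and silencing were not separated by the design. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values of single genes measure only the spread between these libraries, which may be technical. The p-values of gene lists at a preset correlation, of 3' UTR words and of exon overlap, described below, treat genes as the units. They do not measure the spread between libraries.

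Per the labels' protocols, total RNA was purified on poly-T beads, fragmented, copied with random hexamers and sequenced in paired ends. Whether the libraries kept strand information was not given in the sources used here. Per the submitters' processing notes, FastQC 0.11.2, Trimmomatic 0.36, HISAT2 2.0, bedtools 2.26.0 and the genome build hg38 were used. The tool that quantified the genes, the annotation release and the rule by which genes were listed were not given in the sources used here. The deposited table holds 7698 protein-coding genes with 1 value per library, which was taken to be FPKM, fragments scaled to transcript length and to the mapped total of the library. The header names no unit. The reading as FPKM rests on the values, which are never negative, are not whole numbers and sum to 371693 and 376347 in the untreated libraries and to 378204 and 352964 in the siPCBP2 libraries. In another unit normalized to the library total, fold changes would differ by 1 common factor per library, and levels of different genes would not be comparable in the same way.

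The authors' fold (a ratio) equalled the mean of the untreated libraries plus 0.1 over the mean of the siPCBP2 libraries plus 0.1 for all 7698 genes, within a relative tolerance of 1e-06. The authors' p-values and q-values stand beside it, and the test behind them was not given in the sources used here. Of the distinct q-values, 93.8% matched a Benjamini-Hochberg adjustment over 8625 genes, in that the rank they imply was whole within 1e-04. That total was inferred from this match. By it, 927 genes of the adjustment were not analysed here.

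No read counts were used and the sequencing depth is unknown, so no counting interval or detection limit was given. Because FPKM is a relative unit, a shift in abundant transcripts moves all other values; the mitochondrially encoded mRNAs held 29.7% and 31.2% of the summed FPKM in the untreated libraries and 32.3% and 31.1% in the siPCBP2 libraries. Between 5 and 15 genes per library were listed at 0. Values of genes that overlap on a strand, or that have near-identical copies such as histone genes and genes with processed pseudogenes, depend on how the authors' quantifier divided shared fragments.

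Genes with at least 1 FPKM in at least 2 libraries were kept, which left out 9 genes and kept 7689. Values were tested as log2(FPKM + 1) with limma 3.58.1 in R 4.3.3, with empirical Bayes moderation and a trend of the prior variance with the mean, as siPCBP2 minus untreated. The pseudocount of 1 understates the change of genes with low values. Adjusted p-values are Benjamini-Hochberg values over all genes tested, with a threshold of 0.05. All adjusted p-values of genes come from limma and are two-sided. An exact permutation test of 2 libraries against 2 cannot give a two-sided p under 0.333 and was not used for single genes. Means are given with the SD over 2 libraries. On data simulated from these libraries, 200 of 7689 genes were changed in each of 5 runs. The same test recovered 99.8% of the genes changed 4-fold and 86.4% of those changed 2-fold, and 7.55% of its calls were false. The simulated values were independent and normal with the fitted spread, and 200 planted changes ease the adjusted threshold. These rates therefore do not carry over to the data. There, 40 genes were at least 2-fold lower and 30 higher at an unadjusted limma p under 0.05, and 4 genes passed.

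Before the data were examined, 25 gene lists, the tests, the alternatives other than those named below as added and the rule for naming genes were fixed. Of the lists, 23 had at least 3 listed genes and were tested with camera in limma at a preset inter-gene correlation of 0.01, with Benjamini-Hochberg adjustment over the lists. Camera compares a list with all other genes. The estimated correlation within each list and fry, which asks only whether a list's genes move one way on balance, were alternatives. With 4 libraries in 2 groups, the test with an estimated correlation has few degrees of freedom and little power. A list that does not pass it is not thereby shown to be unshifted. Members were also counted after adjustment over the list alone. The genes named are PCBP2, UFD1 and NT5E; then the genes past the threshold whose groups did not overlap and whose mean was at least 2 FPKM, up to 10 in each direction; then, from each list, up to 2 members in each direction past the threshold or otherwise up to 2 members of smallest p as values; and, in a direction with fewer than 5 genes past the threshold, the 5 genes of smallest p that did not pass. Genes named outside this rule are said to be so, and some genes that the rule takes are not reported here.

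Coordinates and gene identifiers are those of the deposited table, in hg38. GENCODE release 29 held 7695 of the 7698 genes, 96% of them with the same start and end, and was used for overlaps of exons on the same strand and for 3' UTR sequences (the longest annotated 3' UTR of each gene). For 3' UTR words of 7 bases carried by at least 100 genes, the fold changes were regressed on presence of the word, adjusted for 3' UTR length and GC content. The word with the most negative z among those in PCBP2 transcripts was set against the most negative z in 1000 permutations of the fold changes over genes (raised from 100 after the result was seen), and the poly(C)-binding motif CCYYCCH (Y, C or T; H, any base but G) was tested with 2000 permutations. In a simulation, 1 word was given a fall of 0.3 in permuted fold changes and was recovered. That fall was larger than the shift reported below, -0.09. The recovery therefore does not show that a shift of that size would be assigned to the right word. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 was used for this part.

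The alternatives were no filter, a filter of at least 5 FPKM in at least 2 libraries, a pseudocount of 0.1, quantile normalization, each library left out in turn, the replicate number as a block, thresholds of 0.01 and 0.1, and the other list tests. Added after seeing the data were scaling to 1 common total, no mean-variance trend, leaving out the genes with the 3' UTR word of the most negative z and leaving out genes that differed over 2-fold between libraries of 1 group. Tests written for counts were planned for the case of a count table and were not run.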

Results

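Poly(A)-selected RNA of MDA-MB-231 cells, a mesenchymal-like triple-negative breast cancer line, was sequenced from 2 untreated libraries and 2 libraries of cells given siPCBP2. The table listed 7698 protein-coding genes in FPKM, with summed values of 371693 and 376347 in the untreated and 378204 and 352964 in the siPCBP2 libraries. Across genes, log2(FPKM + 1) values correlated at a Pearson's r of 0.970 between the untreated libraries and 0.966 between the siPCBP2 libraries, and at 0.950 to 0.956 between libraries of different groups. These correlations are across genes, which are not independent replicates. No gene had an identical value above 0 in both libraries of a group, so each library was counted once. Sequencing depth is unknown because no counts were used.

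The comparison of siPCBP2 with untreated cells asked which transcripts depend on PCBP2, a poly(C)-binding protein that acts in RNA stability, splicing, 3' end formation and translation. PCBP2 mRNA fell 5.83-fold, from 97.1 ± 6.04 FPKM in untreated cells to 16.7 ± 0.0836 FPKM in siPCBP2 cells (SD, n = 2), with values of 101.4 and 92.9 against 16.6 and 16.7. The same cells had less mRNA of SELENOF, a selenoprotein of the endoplasmic reticulum, which fell 4.41-fold from 67.7 ± 5.05 to 15.4 ± 1.20 FPKM. NT5E, the cell-surface enzyme CD73 that makes adenosine from AMP, fell 2.77-fold from 144.3 ± 1.27 to 52.2 ± 2.58 FPKM. HNRNPA3, a nuclear RNA-binding protein, fell 2.67-fold from 87.8 ± 1.04 to 32.9 ± 0.980 FPKM. UFD1, which recognises ubiquitinated proteins in degradation from the endoplasmic reticulum, measured 17.8 ± 1.29 FPKM in untreated and 4.07 ± 0.791 FPKM in siPCBP2 cells, a 4.37-fold lower level that did not pass the threshold.

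By limma, the log2 fold changes on the log2(FPKM + 1) scale were -2.47 (SE 0.11, adjusted p = 0.0119) for PCBP2, -2.07 (SE 0.12, adjusted p = 0.0291) for SELENOF, -1.45 (SE 0.10, adjusted p = 0.0418) for NT5E and -1.39 (SE 0.10, adjusted p = 0.0423) for HNRNPA3. UFD1 had a log2 fold change of -1.90 (SE 0.18, unadjusted p = 7.58e-05, adjusted p = 0.0729). UFD1 and NT5E are the genes that the series title names as regulated by PCBP2; whether the study picked them from these libraries was not given in the sources used here, so their direction here is not taken as independent evidence. PCBP2 (ENSG00000197111) lies on chromosome 12 at 53452102 to 53481162 on the plus strand of hg38, and NT5E (ENSG00000135318) on chromosome 6 at 85449584 to 85495791 on the plus strand. SELENOF (ENSG00000183291) lies on chromosome 1 at 86862445 to 86914424 on the minus strand, HNRNPA3 (ENSG00000170144) on chromosome 2 at 177212563 to 177223958 on the plus strand, and UFD1 (ENSG00000070010) on chromosome 22 at 19449910 to 19479215 on the minus strand. None of these 5 genes shares an exon with another coding gene on its strand, while exons of PCBP2 overlap those of 3 noncoding genes on its strand and exons of HNRNPA3 those of 1.

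**Figure D1:**
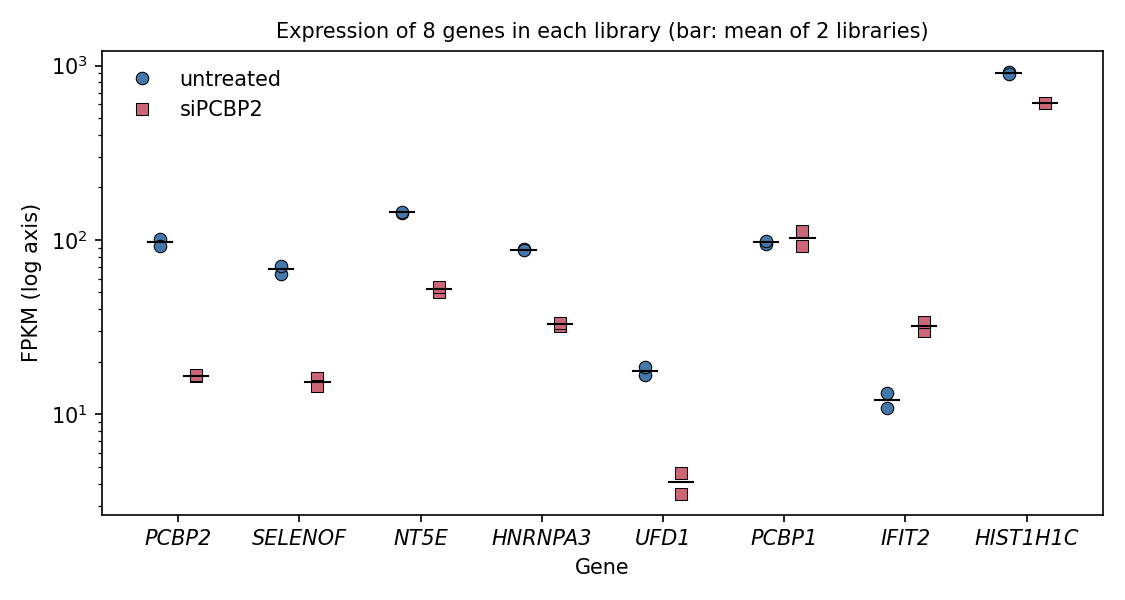
FPKM of 8 genes (horizontal axis) in each library on a log vertical axis, with circles for the 2 untreated libraries, squares for the 2 siPCBP2 libraries and bars for their means. PCBP2 lies at 101.4 and 92.9 FPKM in untreated and at 16.6 and 16.7 FPKM in siPCBP2 libraries, while its paralog PCBP1 has means of 96.7 and 102.6 FPKM; UFD1, IFIT2 and HIST1H1C did not pass the gene-level threshold.

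Over all 7689 genes tested, these 4 genes passed an adjusted p under 0.05, all lower in siPCBP2 cells and all changed at least 2-fold. No gene passed with a higher level: limma called 0 genes higher, with 436 genes higher and 748 lower at an unadjusted p under 0.05, 1184 in all against 384 that chance gives. The authors' deposited table has a lowest q of 0.517 and 653 genes at a p under 0.05, where 385 lie by chance. In the authors' deposited table, the untreated over siPCBP2 fold was 5.80 (p = 0.00185) for PCBP2, 4.29 (p = 0.0158) for UFD1 and 2.76 (p = 0.00588) for NT5E. That fold in the authors' deposited table was 4.39 (p = 0.088) for SELENOF and 2.66 (p = 0.0285) for HNRNPA3. SELENOF was thus not under 0.05 there, even unadjusted. With any 1 library left out, limma called 0 genes, with 632 genes at an unadjusted p under 0.05 without untreated 1, 715 without untreated 2, 1085 without siPCBP2 1 and 1192 without siPCBP2 2. Quantile normalization left 2 calls, PCBP2 and SELENOF, with an adjusted p of 0.0933 for NT5E and for HNRNPA3. With all 4 libraries, limma also called 0 genes without a mean-variance trend (adjusted p = 0.0572 for PCBP2). It called 0 with the replicate number as a block (adjusted p = 0.105 for PCBP2).

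Among genes that did not pass, those with the smallest p and a lower level included HIST1H2BE, ARHGDIB, UFD1 and DYNC1I2. HIST1H2BE measured 25.6 ± 0.981 FPKM in untreated and 8.77 ± 0.544 FPKM in siPCBP2 cells. ARHGDIB measured 60.7 ± 7.02 and 22.8 ± 0.431 FPKM and DYNC1I2, a dynein intermediate chain, 52.2 ± 1.91 and 22.3 ± 1.53 FPKM. Their adjusted p-values by limma ran from 0.0721 to 0.0804. Those with a higher level were AC012184.2, RNF6, IFIT2, SERPINB2 and CS. AC012184.2 measured 0.971 ± 0.386 FPKM in untreated and 10.4 ± 1.23 FPKM in siPCBP2 cells. The ubiquitin ligase RNF6 measured 9.56 ± 0.659 and 24.3 ± 1.17 FPKM and the interferon-induced IFIT2 12.02 ± 1.65 and 31.9 ± 2.62 FPKM. SERPINB2, an inhibitor of urokinase, measured 33.7 ± 0.0577 and 64.7 ± 0.934 FPKM and citrate synthase, CS, 20.2 ± 0.0776 and 51.3 ± 8.79 FPKM. Their adjusted p-values by limma ran from 0.0812 to 0.0955. AC012184.2 shares exons with 2 other coding genes on its strand and SERPINB2 and CS with 1 each, so their values depend on how fragments were divided.

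By camera at the preset correlation, groups of cell-cycle, histone and interferon-stimulated genes shifted as lists, 3 of them lower and 1 higher. With an estimated correlation none of the 4 passed, but 0 of all 23 lists did, and that test has little power with 4 libraries. Replication-dependent histone genes, which package newly made DNA, were lower in siPCBP2 cells for 16 of 16 measured genes, with a median log2 fold change of -0.59 (adjusted p = 9.94e-12, and adjusted p = 0.564 with an estimated correlation). Genes of the G1/S transition and DNA replication were lower for 23 of 26, with a median of -0.31 (adjusted p = 8.30e-06, and adjusted p = 0.404 with an estimated correlation). Genes of G2/M and mitosis were lower for 28 of 31, with a median of -0.27 (adjusted p = 1.90e-05, and adjusted p = 0.404 with an estimated correlation). Interferon-stimulated genes were higher for 15 of 19, with a median of 0.36 (adjusted p = 1.27e-06, and adjusted p = 0.404 with an estimated correlation). Fry gave an adjusted p of 0.0198 for the interferon-stimulated genes and 0.0770 for each of the 3 other lists.

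No single member of these lists passed the threshold over all genes tested by limma, where 16 histone genes, 11 genes of G1/S and 12 of G2/M were lower and 10 interferon-stimulated genes higher at an unadjusted p under 0.05. In the opposite direction, 2 genes of G2/M were higher at that p, FOXM1 and the mitotic kinase AURKA, which measured 45.6 ± 0.447 and 57.4 ± 1.65 FPKM and was named after its values were seen. Adjusted over the list alone, all 16 histone genes passed, among them HIST1H2BD with 408.1 ± 13.2 FPKM in untreated and 253.2 ± 5.34 FPKM in siPCBP2 cells and HIST1H1C with 907.1 ± 14.2 and 612.2 ± 0.196 FPKM. Replication-dependent histone mRNAs mostly end in a stem-loop without a poly(A) tail, while the libraries were poly(A)-selected. Genes of the same histone class can be near-identical copies. These values therefore depend on selection and may depend on how fragments were divided. Of the G1/S list, 1 gene passed adjusted over the list alone, the clamp-loader subunit RFC4 (38.8 ± 2.45 to 23.7 ± 1.15 FPKM), and the helicase subunit MCM6 measured 25.2 ± 0.104 and 17.2 ± 0.899 FPKM. Of the G2/M list, 10 genes were lower and 1 higher adjusted over the list alone. The lower ones included the kinetochore motor CENPE (38.1 ± 3.73 to 21.1 ± 1.81 FPKM) and the proliferation marker MKI67 (96.9 ± 4.77 to 63.4 ± 1.02 FPKM). The higher one was FOXM1, a transcription factor that drives mitotic genes, with 22.8 ± 0.141 and 31.1 ± 2.80 FPKM, named after its values were seen. Adjusted over the list alone, 7 interferon-stimulated genes were higher and none lower, led by IFIT2 and by IFIT3, which measured 33.0 ± 0.692 and 59.6 ± 1.90 FPKM. PCBP2 is known to restrain signalling through MAVS, which mRNA levels of the genes for RNA sensing and MAVS signalling do not measure. Those genes did not pass as a list by camera (median -0.0049, 6 of 12 higher, adjusted p = 0.793). IFIH1, a sensor of double-stranded RNA, measured 5.38 ± 0.764 and 8.91 ± 1.27 FPKM and the kinase IKBKE 15.2 ± 0.831 and 10.7 ± 1.51 FPKM.

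**Figure D2:**
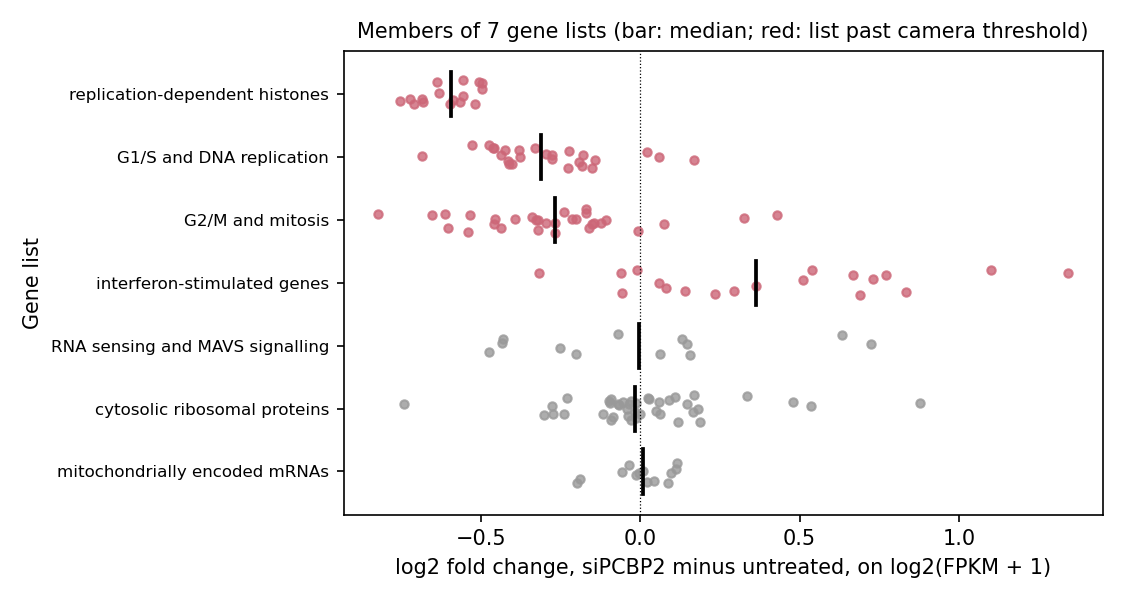
Log2 fold changes, siPCBP2 minus untreated, on the log2(FPKM + 1) scale (horizontal axis) for the members of 7 gene lists (vertical axis), with 1 point per gene, a bar at each median and red for lists past the camera threshold. All 16 histone genes lie below 0 with a median of -0.59, and the interferon-stimulated genes have a median of 0.36.

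The lists closest to the functions of PCBP2 did not pass camera, and no member passed over all genes tested; HNRNPA3, the hnRNP gene that passed, was not in these lists. Of its paralogs, PCBP1 measured 96.7 ± 2.69 FPKM in untreated and 102.6 ± 13.8 FPKM in siPCBP2 cells and HNRNPK 237.0 ± 15.0 and 209.3 ± 10.5 FPKM. The 3 paralogs had a median log2 fold change of 0.08 (adjusted p = 0.964), and the fold change of PCBP1 turned to -0.06 without siPCBP2 replicate 1. Other hnRNP and splicing regulators were lower for 21 of 25 genes with a median of -0.15 (adjusted p = 0.113). HNRNPD measured 161.7 ± 22.6 and 108.5 ± 19.7 FPKM and RBFOX2 46.9 ± 1.87 and 36.6 ± 0.173 FPKM. Cleavage and polyadenylation factors had a median of -0.05 over 17 genes (adjusted p = 0.793). RBBP6 measured 25.0 ± 1.55 and 20.1 ± 0.485 FPKM and CSTF2 15.3 ± 1.00 and 12.2 ± 0.359 FPKM. The partners of UFD1 in ubiquitin-dependent degradation from the endoplasmic reticulum had a median of 0.04 over 17 genes (adjusted p = 0.749). EDEM3, which trims glycans of misfolded proteins, measured 8.58 ± 0.681 and 14.2 ± 0.387 FPKM and DERL1, a membrane component, 20.4 ± 1.47 and 26.0 ± 3.36 FPKM. The unfolded protein and integrated stress response list had a median of -0.11 over 17 genes (adjusted p = 0.793). Adjusted over the list alone, 2 of its genes were higher and 1 lower. The higher ones were the cystine transporter SLC7A11 (13.4 ± 0.0520 to 23.4 ± 2.38 FPKM) and PPP1R15A, named after its values were seen (87.5 ± 0.479 to 117.8 ± 3.85 FPKM). The lower one was the mTOR inhibitor DDIT4 (16.1 ± 1.46 to 8.05 ± 0.107 FPKM). The extracellular adenosine pathway around NT5E had a median of 0.02 over 6 genes (adjusted p = 0.793), and 2 genes were lower adjusted over the list alone. These were ENPP1, which makes AMP from ATP outside the cell (25.5 ± 0.0862 to 17.1 ± 0.671 FPKM), and the adenosine receptor ADORA2B (44.3 ± 1.54 to 33.2 ± 2.22 FPKM).

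Lists of cell fate, adhesion and invasion did not pass either. In the mesenchymal list (20 genes, median -0.03, adjusted p = 0.867), 2 genes were lower adjusted over the list alone. These were the matrix protein THBS1 (189.8 ± 0.583 to 103.5 ± 1.51 FPKM) and the growth factor CTGF (70.0 ± 3.51 to 38.6 ± 0.879 FPKM). In the epithelial list (8 genes, median -0.14, adjusted p = 0.631), 1 gene was lower adjusted over the list alone, KRT18 (85.9 ± 0.545 to 45.4 ± 0.733 FPKM). EPCAM measured 5.08 ± 0.334 and 3.43 ± 0.580 FPKM. Among matrix proteases and inhibitors (14 genes, median -0.21, adjusted p = 0.793), SERPINB2 was higher and urokinase, PLAU, lower (92.4 ± 15.0 to 54.8 ± 0.993 FPKM) adjusted over the list alone, 1 gene each way. In the p53 and CDK inhibitor list (11 genes, median -0.0038, adjusted p = 0.793), 3 genes were higher and 1 lower adjusted over the list alone. The higher ones were GADD45A (19.98 ± 2.15 to 33.5 ± 3.04 FPKM), PMAIP1 (33.1 ± 0.374 to 49.1 ± 2.89 FPKM) and AEN. The lower one was CDKN2C, and AEN and CDKN2C were named after their values were seen. Apoptosis regulators had a median of 0.06 over 15 genes (adjusted p = 0.793) and 0 calls adjusted over the list alone. By limma, 1 was higher and 1 lower at an unadjusted p under 0.05, BAK1 (11.3 ± 0.0715 to 16.3 ± 1.01 FPKM) and BID (11.7 ± 1.47 to 8.18 ± 0.412 FPKM).

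In the NF-kB and cytokine list (19 genes, median -0.12, adjusted p = 0.954), 4 genes were lower and 2 higher adjusted over the list alone. The lower ones were TNFAIP2 (24.4 ± 3.66 to 10.1 ± 1.96 FPKM), CSF3 (47.4 ± 6.71 to 27.0 ± 0.632 FPKM), IL11 and CXCL1. The higher ones were TNFAIP3 and CSF2, and these and IL11 and CXCL1 were named after their values were seen. Cholesterol synthesis genes were lower for 12 of 18 with a median of -0.22 (adjusted p = 0.329 by camera and 0.0470 by fry). Adjusted over the list alone, 3 of them were lower, including SC5D (15.3 ± 0.0496 to 7.51 ± 1.40 FPKM) and INSIG1, and 1 was higher, EBP. INSIG1 and EBP were named after their values were seen. In the iron list (16 genes, median 0.09, adjusted p = 0.631), 1 gene was lower adjusted over the list alone, the transferrin receptor TFRC (112.9 ± 6.77 to 68.0 ± 9.66 FPKM). Ferritin heavy chain, FTH1, measured 1079.3 ± 28.5 and 922.4 ± 13.1 FPKM. NRF2 targets had a median of -0.07 over 11 genes (adjusted p = 0.793). SRXN1 measured 30.4 ± 0.435 and 22.3 ± 1.19 FPKM and NQO1 37.8 ± 1.55 and 28.3 ± 2.43 FPKM. Hypoxia and glycolysis genes had a median of -0.14 over 23 genes (adjusted p = 0.631). VEGFA measured 74.2 ± 12.3 and 48.3 ± 5.88 FPKM and ENO1 508.0 ± 4.32 and 428.5 ± 8.59 FPKM.

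Cytosolic ribosomal proteins had a median of -0.02 over 41 genes (adjusted p = 0.761) and passed as higher after quantile normalization (adjusted p = 0.00594). RPL18 measured 191.0 ± 17.2 and 276.6 ± 2.33 FPKM and RPS23 143.9 ± 17.9 and 200.4 ± 12.04 FPKM. Mitochondrially encoded mRNAs had a median of 0.0088 over 13 genes (adjusted p = 0.793). MT-CO3 measured 7274.1 ± 230.9 and 6333.3 ± 331.0 FPKM and MT-ND6 448.9 ± 35.6 and 393.3 ± 11.9 FPKM. Median and camera direction had opposite signs for the ribosomal, RNA sensing, p53 and adenosine lists. Median and mean did so for the ribosomal, p53 and adenosine lists, the PCBP2 paralogs and the mitochondrial mRNAs. The median log2 fold change of all genes tested was -0.04. Of markers of other cell types, 0 of 14 immune and blood genes and 1 of 14 stromal and endothelial genes were listed, so neither list was tested. That gene, FABP4, measured 0.604 ± 0.163 FPKM in untreated and 2.50 ± 1.29 FPKM in siPCBP2 cells (unadjusted p = 0.0470 by limma, adjusted p = 0.318).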

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

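Scaling to 1 common total, no mean-variance trend and leaving out genes with the 3' UTR word or with a large spread within a group were chosen after seeing the data. All other alternatives were planned. The 4 genes past the threshold kept their calls without a filter, with the stricter filter and with a pseudocount of 0.1. The count of 4, all at least 2-fold changed, moved to 2 (2 at least 2-fold) under quantile normalization and under scaling to 1 common total, PCBP2 and SELENOF in both. It was 0 (0 at least 2-fold) by limma without a mean-variance trend, with 1220 genes at an unadjusted p under 0.05. With any 1 library left out it called 0 genes (0 at least 2-fold), with 632 to 1192 genes at an unadjusted p under 0.05; the lone library was assumed to vary like the other group. A threshold of 0.01 gave 0 genes, with 1184 at an unadjusted p under 0.05, and a threshold of 0.1 gave 22, of which 7 were higher and 15 lower. Without genes that differed over 2-fold between libraries of 1 group, 31 genes passed, 10 higher and 21 lower, 21 of them at least 2-fold; this setting narrows the pooled spread by its own construction. Without carriers of the 3' UTR word, 3 passed, because HNRNPA3 carries it and was left out.

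The log2 fold change of PCBP2 was -2.54 to -2.41 with a library left out (adjusted p from 0.0559 to 0.326) and -2.47 without a mean-variance trend (adjusted p = 0.0572). That of NT5E was -1.50 to -1.40 with a library left out (adjusted p from 0.103 to 0.330), -1.41 under quantile normalization (adjusted p = 0.0933), -1.42 under scaling to 1 common total (adjusted p = 0.0605) and -1.45 without a mean-variance trend (adjusted p = 0.0772). That of UFD1, -1.90, passed 0.05 only without genes that differed over 2-fold within a group (adjusted p = 0.0173, over a range of 0.0173 to 0.460), and UFD1 was among the 22 genes at the threshold of 0.1. That of PCBP1 was -0.06 (-0.0585) to 0.22 with a library left out. Calls lost with a library left out had fewer samples; the cause of the other losses was not tested.

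The histone, G1/S, G2/M and interferon-stimulated lists passed in the same direction under every alternative to the gene test, filter, scaling and libraries used. With an estimated correlation their adjusted p was 0.564 for the histones and 0.404 for G1/S, for G2/M and for the interferon-stimulated genes. By fry it was 0.0770 for the histones, 0.0770 for G1/S, 0.0770 for G2/M and 0.0198 for the interferon-stimulated genes. Cholesterol biosynthesis passed by fry (0.0470) and the ribosomal proteins under quantile normalization (0.00594). Lists that did not pass turned direction in some settings; the cause was not tested. With a library left out their adjusted p ran from 0.880 to 0.940 for the poly(C)-binding paralogs, 0.624 to 0.923 for p53 targets, 0.285 to 0.923 for mitochondrial mRNAs, 0.694 to 0.974 for cleavage and polyadenylation factors, 0.490 to 0.942 for apoptosis regulators, 0.778 to 0.940 for NF-kB and cytokines and 0.153 to 0.881 for ribosomal proteins. The mesenchymal list turned under quantile normalization (0.978), the paralogs (1.00) and p53 targets (1.00) without the word's carriers, and the paralogs (0.978) and mitochondrial mRNAs (0.978) by fry.

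With the replicate number as a block, limma called 0 genes (0 at least 2-fold), with 940 at an unadjusted p under 0.05, and gave -2.47 for PCBP2 (adjusted p = 0.105) and -1.45 for NT5E (adjusted p = 0.249). The 4 lists passed camera under the block at the preset correlation; with an estimated correlation and no block their adjusted p was 0.404 to 0.564. Same-numbered libraries had deviations that correlated at -0.0888 across genes. This single value cannot exclude a shared culture or day, and the labels do not say whether the number marks one. Of 763 values of 59 named genes under the alternatives, 720 kept direction and side of the threshold and 1 turned. Alternatives written for counts were not run, since the values are not counts. Depth is unknown, so its limit on low genes could not be given.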

Other observations

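The tests of overlapping gene models, of the sites in NT5E and SELENOF, of the other words beyond the limit and of MT-ND6, and the gene groups of the next paragraph, were chosen after the results were seen; the tests of seed matches, of the poly(C)-binding motif, of scaling and of transfection were not.

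Outside the fixed list, 27 further clustered histone genes were measured, 26 of them lower in siPCBP2 cells, with a median log2 fold change of -0.52; by limma 0 passed and 22 were lower at an unadjusted p under 0.05. Of 9 histone variant genes, most of which are made from polyadenylated mRNA, 6 were lower, with a median of -0.22. By limma 0 passed and 3 were lower at an unadjusted p under 0.05. These were the linker histone H1F0 (67.0 to 41.0 FPKM), H2AFV and CENPA, and CENPA is also a member of the G2/M list. Genes between adjusted p-values of 0.05 and 0.1 by limma included, as lower ones, the phosphate transporter SLC20A1 (111.6 ± 3.23 to 59.6 ± 0.785 FPKM) and the transmembrane collagen COL13A1 (39.2 ± 0.710 to 18.5 ± 1.82 FPKM). Higher ones included SAT1, which acetylates polyamines for export or breakdown (19.3 ± 0.148 to 38.0 ± 0.866 FPKM), and the matrix protein ABI3BP (3.70 ± 0.503 to 11.8 ± 0.596 FPKM). MYC measured 6.13 and 7.42 FPKM in the untreated and 105.4 and 42.9 FPKM in the siPCBP2 libraries (log2 fold change 3.14, SE 0.41, adjusted p = 0.108 by limma), with a 2.46-fold difference between the siPCBP2 libraries.

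One pattern is that falls beside PCBP2 may come in part from the silencing RNA acting on other mRNAs through its seed. Among 2658 words of 7 bases found in PCBP2 transcripts, GTGTCAA had the most negative z (-6.35; permutation p = 0.001, the smallest that 1000 permutations give), with a shift of -0.09 on the log2 scale (95% interval -0.12 to -0.06, not adjusted for the choice of the word) in the 606 of 7578 genes that carry it in the 3' UTR. GTGTCAA was not the only one, since 4 words of PCBP2 transcripts lay beyond the 5% limit of the permutations (z = -4.11). The others were AAGGAAA (-5.29), CAAGGAA (-4.56) and TGTGTCA (-4.23). These words overlap as shifted frames, TGTGTCA with GTGTCAA and CAAGGAA with AAGGAAA, so they are not 4 separate results. GCGTCAT, which PCBP2 transcripts lack, had a z of -5.06. It came from all 14792 words tested, while the limit was taken over the 2658 words of PCBP2 transcripts. The sequence of the silencing RNA is not known here, so a seed effect of any of these words stays a hypothesis. NT5E and SELENOF have 0 sites of GTGTCAA in their longest annotated 3' UTRs and HNRNPA3 has 1. For NT5E and SELENOF this argues against GTGTCAA in those 3' UTRs. They share exons with 0 genes on their strand in the annotation used here, which argues against reads shared with overlapping models of that annotation. It cannot exclude shared reads, because the annotation and the quantifier of the authors are not known. Other words stay open for NT5E, which has 1 site of AAGGAAA and 2 of CAAGGAA. SELENOF has 0 sites of each word named here, but other words and other regions were not searched, so a seed effect stays open there too. Both explanations stay open for HNRNPA3, which overlaps 1 noncoding gene on its strand. The poly(C)-binding motif CCYYCCH was present in the longest annotated 3' UTR of 5248 of 7578 genes. These genes were not lower as a group (shift 0.02, 95% interval -0.0029 to 0.04, two-sided permutation p = 0.0885). That argues only against a broad fall of genes with at least 1 such word there. Most genes carry the motif, so its presence separates them weakly, and the number of sites and other regions were not tested. Loss of PCBP2 acting on single mRNAs stays open and untested.

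Another pattern is the genes that differed over 2-fold between libraries of 1 group on the log2(FPKM + 1) scale, 242 of 7686. Reads shared with overlapping gene models on the same strand are a candidate explanation for part of them. Of these genes, 31.4% shared exons with another coding gene on their strand against 10.4% of the others (odds ratio 3.94, two-sided Fisher's exact p = 2.88e-18). The odds ratio was 3.58 over 5 bins of level. Genes that overlap one another can trade the same reads and then both count. They are not independent units, so this p can overstate the evidence. TXNDC5 measured 118.7, 17.6, 26.8 and 101.3 FPKM and its readthrough neighbour BLOC1S5-TXNDC5 0.578, 82.5, 75.0 and 0, in the order untreated 1, untreated 2, siPCBP2 1 and siPCBP2 2, while their sums were 119.3, 100.1, 101.8 and 101.3. Of the 242 genes, 64.5% share no exon with any gene on their strand in the annotation used here. An example is B2M (304.3 and 39.6 FPKM in untreated, 229.3 and 316.3 FPKM in siPCBP2 libraries). For these genes that annotation gives no sign of shared reads of this kind. It cannot exclude them, because the annotation and the quantifier of the authors are not known. Overlaps on the opposite strand and reads shared with near-identical copies were not tested. No biological explanation was tested, since the labels name no difference between libraries of a group.

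The last pattern is the shift of the histone, G1/S, G2/M and interferon-stimulated lists, which passed camera at the preset correlation only. By fry, the interferon-stimulated list passed (adjusted p = 0.0198) and the 3 other lists did not (adjusted p = 0.0770 each). With an estimated correlation, where camera has little power with 4 libraries, the adjusted p was 0.564 for the histones and 0.404 for each of the others. At the preset correlation all 4 lists passed camera in the same direction after quantile normalization (highest adjusted p = 4.74e-05). Camera compares a list with all other genes, so a factor common to a library moves both nearly alike. That outcome was largely set beforehand and adds no evidence on different scaling of the libraries. Whether the shifts come from transfection itself rather than loss of PCBP2 cannot be told apart, because 0 libraries were transfected with another RNA and the controls were untreated. For the histones, less carry-over of RNA without poly(A) tails also stays open: MT-ND6, the other listed mRNA known to lack such a tail, had a log2 fold change of -0.19 (95% interval -0.45 to 0.07), and 1 gene decides nothing. A lower share of dividing cells after silencing of PCBP2 is a biological explanation that was not tested.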
